A study of Homo sapiens with 6 samples.

How the data were processed

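RNA was measured in 6 libraries of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels, 3 libraries came from cells transfected with a plasmid for the adenine base editor SpRY-Cas9-ABE8e together with guides against the splice acceptor and splice donor of APP exon 17, and 3 from cells given a GFP plasmid. Per the labels' protocols, RNA was extracted with RNeasy columns, polyA-selected, made into TruSeq mRNA libraries and sequenced on a NovaSeq instrument. HISAT2, featureCounts and limma are named in the submitters' processing notes, without versions. The genome build, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here.

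The authors deposited raw read counts per gene for 62700 Ensembl gene IDs, not normalized, with 1 column per library. Columns were assigned to libraries by the names in the sample descriptions. The authors also deposited a comparison table with log2 fold changes, average log2 expression, p-values and adjusted p-values. Its first 15273 rows hold that comparison. After 2 empty rows come 47425 rows that repeat entries of the count table under the same headings, and these were left out. Gene symbols were looked up by ID, and 42343 of the IDs had a symbol.

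Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter and the quasi-likelihood F-test, editor minus GFP, with Benjamini-Hochberg adjustment. The filter left 20511 genes. Standard errors were taken as the log2 fold change divided by the square root of F, with 95% intervals. CPM are counts scaled to library size with TMM, and log2 CPM used a prior count of 2. The threshold was an adjusted p of 0.05, and calls were also counted at a 2-fold change. The titles number the replicates and call them biological, but nothing says that they came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical. An exact permutation test of 3 against 3 cannot go below p = 0.1.

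The 31 gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry. The lists covered Alzheimer's disease risk, amyloid processing, DNA repair, stress, interferon, inflammation, cell cycle, metabolism, ribosome, mitochondria, RNA processing and markers of other cell types. The lists, the comparisons, the main test and the alternatives were fixed before the data were examined. The genes named in the text were APP and a set of repair genes that included MPG, UNG, MSH6 and PMS2; some genes of that set are not reported here. To these were added, among genes past the threshold with an average log2 CPM of at least 1 and groups that did not overlap, the 10 largest and 10 lowest changes and the 5 smallest p per direction, and up to 4 members with the smallest p per list. HSPA7, RPL21, RPL21P29, RPL21P120, the genes overlapping the 5 calls, HSPA1A, HSPA1B, PRPF8 and TREM2 lie outside this rule and were chosen after their values were seen.

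Alternatives were RLE scaling, library totals, no filter, at least 50 reads in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p of 0.01 and leaving out each library in turn. Summing editor libraries 2 and 3 was added after seeing the data. The edgeR, DESeq2 and limma-voom fits were tested on simulated counts for the 20511 genes, 3 against 3. The other alternatives, the fit without the low-count filter among them, were not simulated, so their share of false calls is unknown. The edgeR test recovered 8% of genes changed by a log2 of 0.5, 70% at 1, 98% at 2 and 100% at 4, with 9 false among 149 calls. On the same simulated counts DESeq2 made 39 false calls among 192 and limma-voom 10 among 148. Camera recovered a shift of -0.4 in a list of 30 genes and called 0 of 50 unchanged lists. The genes were simulated independently, so this does not cover lists whose members move together, such as ribosomal genes (estimated correlation 0.90).

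Pseudogenes were aligned to the transcripts of their parent genes with Biopython 1.88, using GENCODE release 29. Coordinates come from that release on GRCh38, matched by gene ID. Pseudogenes entered when at least 80% of their length aligned with at most 30 differences and the parent had an average log2 CPM of at least 5. The permutation test shuffled fold changes within parents 100000 times. Exon-level reads, junctions and base changes in the RNA were not analysed here.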

Results

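Gene expression was measured in HEK293T cells given the adenine base editor with guides at APP exon 17 (3 editor libraries) or a GFP plasmid (3 GFP libraries). SpRY-Cas9-ABE8e joins a Cas9 variant with few limits on its target site to a deaminase that changes adenine to guanine in DNA. The editor libraries held 110519197, 124265010 and 152625595 counts, and the GFP libraries 128988337, 128223446 and 124681733. The editor libraries 2 and 3 were much closer to each other than other replicates, with a chi-square per degree of freedom of 3.41 against 35.8 to 200.6 for the other pairs within groups. Editor library 1 lay closer to GFP libraries 2 and 3 (81.4 and 44.5) than to editor libraries 2 and 3 (119.8 and 128.5). The difference between editor libraries 2 and 3 exceeded sampling noise. They were kept as 2 replicates as the labels number them, but the counts do not show whether they came from separate cultures. The first principal component, with 40.8% of the variance, parted these 2 libraries from the other 4. Mitochondrially encoded genes took 4.62%, 6.39% and 6.32% of the counts in the editor libraries, against 3.66%, 4.49% and 3.42% in the GFP libraries.

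The first question was whether the editor altered expression of its target. APP (ENSG00000142192.22), the precursor of the amyloid beta peptide, lies on chromosome 21 from 25880550 to 26171128 on the minus strand (GRCh38). Its exon 17 spans 25891722 to 25891868, 147 nucleotides of a transcript of 18 exons. APP stood at 446 ± 54.3 CPM in the editor libraries and 495 ± 33.3 CPM in the GFP libraries (SD, n = 3 each). The log2 fold change was -0.15 (SE 0.12, 95% interval -0.43 to 0.13, adjusted p = 0.752 by edgeR), so no difference in total APP was detected. The log2 fold change was -0.28 without editor library 1 (adjusted p = 0.165) and -0.10 without editor library 2 or editor library 3. The authors' deposited table gives a log2 fold change of -0.14 for APP with an adjusted p of 0.784. A count per gene does not tell transcripts with exon 17 from transcripts without it, so skipping of the exon was not analysed here.

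**Figure D1:**
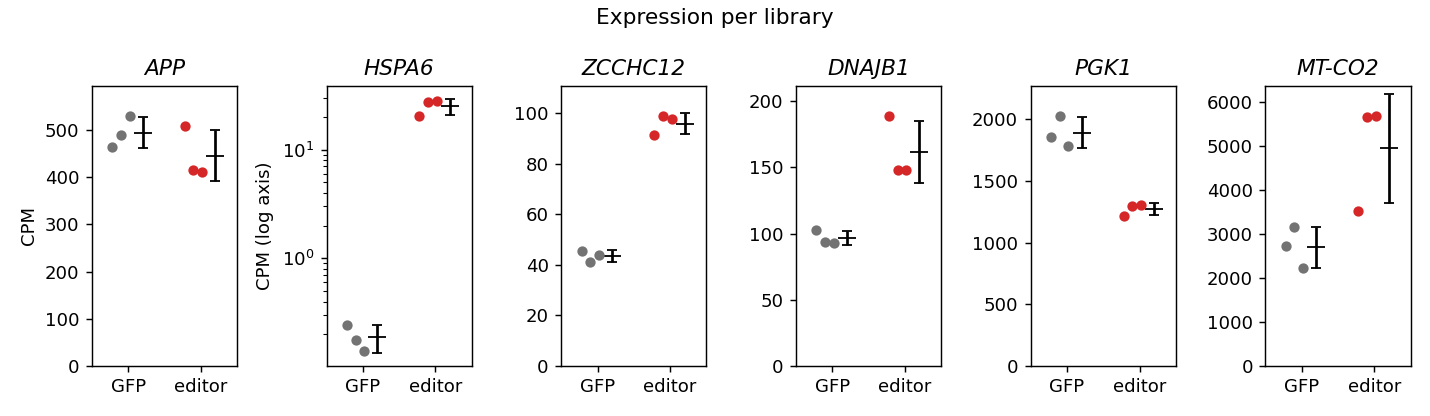
CPM (vertical axis, from 0 except for the log axis of HSPA6) in each GFP and editor library, with the mean and SD of the 3 libraries beside the points. HSPA6 and ZCCHC12 passed the test over all genes, with log2 fold changes of 7.05 and 1.14, and APP, DNAJB1, PGK1 and MT-CO2 did not.

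Across all 20511 genes, 5 rose in the editor libraries and 0 fell. HSPA6, a strictly inducible member of the HSP70 chaperone family on chromosome 1 (161524540 to 161526910), rose from 0.188 ± 0.0535 to 25.2 ± 4.29 CPM (SD, n = 3 each), a log2 fold change of 7.05 (SE 0.24, adjusted p = 8.45e-06). It lies within a longer non-coding gene on the same strand. ZCCHC12, a zinc finger protein gene on chromosome X (118823790 to 118826968), rose from 43.5 ± 2.34 to 95.9 ± 4.08 CPM, a log2 fold change of 1.14 (SE 0.10, adjusted p = 0.0144). The other calls were weakly expressed and are named after their values were seen. HSPA7, a near-identical unprocessed pseudogene of HSPA6, had 185 reads in the editor and 2 in the GFP libraries (adjusted p = 0.0144), a ratio of 87.6 with an exact 95% counting interval of 23.9 to 729. RPL21P29 had 270 against 7 reads (adjusted p = 0.0149), a ratio of 36.5 with an interval of 17.5 to 91.7. RPL21P120 had 230 against 49 reads (log2 fold change 2.16, adjusted p = 0.0281). Both are processed pseudogenes of the ribosomal protein gene RPL21, and each lies within a protein-coding gene on the opposite strand (HSPG2 for RPL21P29 and C17orf51 for RPL21P120), so their counts are uncertain. All 5 calls exceeded a 2-fold change. At an unadjusted p under 0.05 there were 1252 higher and 528 lower genes, 1780 in all, where chance gives about 1026. That number was 4777 without editor library 1, 726 without editor library 2 and 750 without editor library 3. Of the splits that mix the groups, 2 gave 4061 and 4384 and the rest 104 to 829. An excess over chance is therefore not specific to the groups, though most mixed splits gave none. The count depended on the libraries and the tool. Without editor library 1 there were 159 higher and 54 lower calls, without the low-count filter 178 and 129, and with DESeq2 47 and 32. There were 3 higher and 1 lower without GFP library 1, 1 higher without GFP library 2, 1 higher and 1 lower without GFP library 3, and 3 higher with limma-voom. HSPA6 was called in all of these fits, whereas ZCCHC12 was not called without editor library 3, GFP library 2 or GFP library 3, with adjusted p from 0.017 to 0.129 over the libraries left out. The calls of HSPA7 and RPL21P29 ended without GFP library 2 (adjusted p = 0.108 for both) or GFP library 3 (0.125 and 0.129), that of HSPA7 also without GFP library 1 (0.218), and that of RPL21P120 without any library but editor library 1. With limma-voom neither RPL21P29 (adjusted p = 0.0764) nor RPL21P120 (0.0631) was called, and the authors' adjusted p for RPL21P29 is 0.154. The authors' deposited table calls 3 genes, HSPA6, ZCCHC12 and RPL21P120, and all 3 were among the 5. Its fold changes correlated with those computed here across 15273 genes (Pearson r = 0.989, genes not being independent replicates).

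Heat shock genes other than HSPA6 moved less. DNAJB1, a co-chaperone of HSP70, stood at a log2 fold change of 0.74 (SE 0.13) and HSPH1, a nucleotide exchange factor of HSP70, at 0.49 (SE 0.13). Of 20 measured heat shock and chaperone genes, 3 were higher adjusted over the list alone (HSPA6, DNAJB1 and HSPH1) and 1 over all genes. The list did not pass camera (adjusted p = 0.0742), but did with DESeq2, limma-voom, library totals, the stricter filter, and without editor library 2 (adjusted p = 0.00452) or editor library 3 (adjusted p = 0.00455). With an estimated correlation its adjusted p was 0.728, and without HSPA6 the mean difference of the list was 0.05 (unadjusted camera p = 0.238). DNAJB1 passed over all genes with DESeq2 (adjusted p = 0.00128), without the low-count filter (adjusted p = 0.0009) and without editor library 1 (adjusted p = 0.0469). The main inducible HSP70 genes HSPA1A and HSPA1B were counted at 4 reads or fewer in every library and were not tested. Both lie on chromosome 6 between 29 and 33 Mb, where 85.0% of protein-coding genes averaged under 10 reads per library, so these counts do not show whether they were expressed or induced.

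The series also asked about genes linked to Alzheimer's disease. Among 52 measured risk genes, 0 passed over all genes and 0 adjusted over the list alone. APOE, a lipid carrier, had a log2 fold change of 0.52 (SE 0.16), CLU, a secreted chaperone, 0.33 (SE 0.10), INPP5D, a phosphatase of inositol lipids, -0.58 (SE 0.18) and ABCA1, a cholesterol exporter, 0.54 (SE 0.20, and 0.31 to 0.70 over the libraries left out), each with an adjusted p of at least 0.504. INPP5D passed without the low-count filter (log2 fold change -0.64, adjusted p = 0.0266), a fit that was not tested on simulated counts. The list as a whole did not differ from other genes by camera (adjusted p = 0.979). Nor did the 33 genes of amyloid precursor processing and clearance (adjusted p = 0.793), of which 0 passed over all genes or adjusted over the list alone. For both lists the mean log2 fold change was above 0 and the median below 0. TREM2, a microglial receptor gene, had 0 reads in every library and was not tested.

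For DNA repair, which the series also asked about, 0 members of the repair lists passed over all genes. MPG, the glycosylase that removes hypoxanthine, had a log2 fold change of -0.19 (SE 0.15), or -0.02 without GFP library 1 and -0.29 without GFP library 2, and UNG, the uracil glycosylase, -0.08 (SE 0.12). Of the mismatch repair genes, MSH6 stood at -0.31 (SE 0.12, adjusted p = 0.543) and PMS2 at 0.10 (SE 0.13, adjusted p = 0.868). The base-excision repair list was lower than other genes by camera (mean log2 difference -0.15, adjusted p = 0.00321), with 24 of 34 members below 0 and POLE2, APEX2 and LIG3 having the smallest p. The mean log2 fold change of its members was smaller, at -0.09. The mismatch repair list was also lower (mean log2 difference -0.17, adjusted p = 0.00362), with 18 of 23 members below 0 and RFC4 and MSH6 having the smallest p. Both lists hold POLD4, the lowest member of each (log2 fold change -0.42), so they overlap and are not independent results. Adjusted over the list alone, 0 members passed in either list, and 0 over all genes. With an estimated correlation the adjusted p was 0.523 for base-excision repair and 0.173 for mismatch repair, so neither call held. That correlation was 0.13 for base-excision repair and -0.014 for mismatch repair. The second lies below the preset 0.01, so members moving together do not explain the loss of the mismatch call. By fry the mismatch list passed (adjusted p = 0.0148) and the base-excision list did not (adjusted p = 0.464). The base-excision call was also lost without GFP library 1 (mean log2 difference -0.11, adjusted p = 0.176). Nucleotide-excision repair (adjusted p = 0.0818), double-strand break repair (adjusted p = 0.147) and p53 targets (adjusted p = 0.233) did not pass, although double-strand break repair was called without GFP library 1 (mean log2 difference -0.20, adjusted p = 0.000502, against -0.10 with all libraries and -0.04 without GFP library 2, where the adjusted p was 0.845).

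The list with the smallest p was that of hypoxia and glycolysis genes, which were lower in the editor libraries. All 30 measured members had a log2 fold change below 0, with a mean difference of -0.46 from other genes (camera adjusted p = 8.52e-21), though the adjusted p was 0.0756 with an estimated correlation. Of these, 20 were lower adjusted over the list alone and 0 over all genes. The glycolytic enzyme genes PGK1, ENO1 and GAPDH stood at -0.57 (SE 0.10), -0.56 (SE 0.11) and -0.64 (SE 0.13), and ANKRD37, an ankyrin repeat gene, at -0.55 (SE 0.11). These 4 genes passed over all genes with DESeq2 (adjusted p from 0.000915 to 0.015) and without the low-count filter (adjusted p from 0.00735 to 0.0304), and GAPDH also without editor library 1 (adjusted p = 0.0447). GAPDH, often used as a reference gene, averaged 3119 CPM in the editor libraries and 4860 CPM in the GFP libraries.

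Mitochondrially encoded genes were higher, with all 13 above 0 and a mean difference of 0.54 (camera adjusted p = 2.63e-09, but adjusted p = 0.415 with an estimated correlation). Of these, 11 were higher adjusted over the list alone and 0 over all genes, among them MT-ATP6 at 0.73 (SE 0.15) and MT-CO2 at 0.88 (SE 0.20). Both passed over all genes with DESeq2 (adjusted p of 0.00943 and 0.0174), without the low-count filter (0.00793 and 0.000361) and without editor library 1 (0.0447 and 0.0407). Cytosolic ribosomal protein genes were lower by camera (mean difference -0.21, adjusted p = 1.04e-09, and adjusted p = 0.728 with an estimated correlation), with 69 of 72 below 0. Their mean difference was -0.10 without GFP library 1 (adjusted p = 0.0156). The nuclear-encoded respiratory chain genes were lower too (adjusted p = 0.000363, and 0.728 as adjusted p with an estimated correlation). Fibroblast genes, of which 11 of 14 were measured, were higher by camera (mean difference 0.27, adjusted p = 0.000363, and adjusted p = 0.173 with an estimated correlation). Of the 11, 8 were above 0 and 3 below. Adjusted over the list alone 4 were higher (LUM, POSTN, PDGFRB and COL3A1), and 0 over all genes. POSTN and PDGFRB were weakly expressed, with 27 to 85 and 27 to 73 reads per library. Interferon-stimulated genes, of which 31 of 45 were measured, were higher (mean difference 0.19, adjusted p = 0.00412, and adjusted p = 0.415 with an estimated correlation). Adjusted over the list alone 2 were higher, GBP1 and OASL, and 0 over all genes. GBP1 had 10 to 44 reads per library and OASL 26 to 98, so both were weakly expressed. Both passed over all genes without the low-count filter (adjusted p of 0.00704 and 0.0199), and OASL without editor library 1 (adjusted p = 0.0407). Immediate-early genes were higher (mean difference 0.13, adjusted p = 0.00846, and adjusted p = 0.592 with an estimated correlation), with EGR1 at 0.77 (SE 0.21). Without editor library 1 the mean difference of the list was -0.03, whereas EGR1 stood at 0.96 and passed over all genes (adjusted p = 0.0362), as it did without the low-count filter (adjusted p = 0.00964). Without GFP library 2, neither the interferon list (adjusted p = 0.0939) nor the immediate-early list (adjusted p = 0.19) was called, and the interferon list was not called without the low-count filter (adjusted p = 0.0773).

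**Figure D2:**
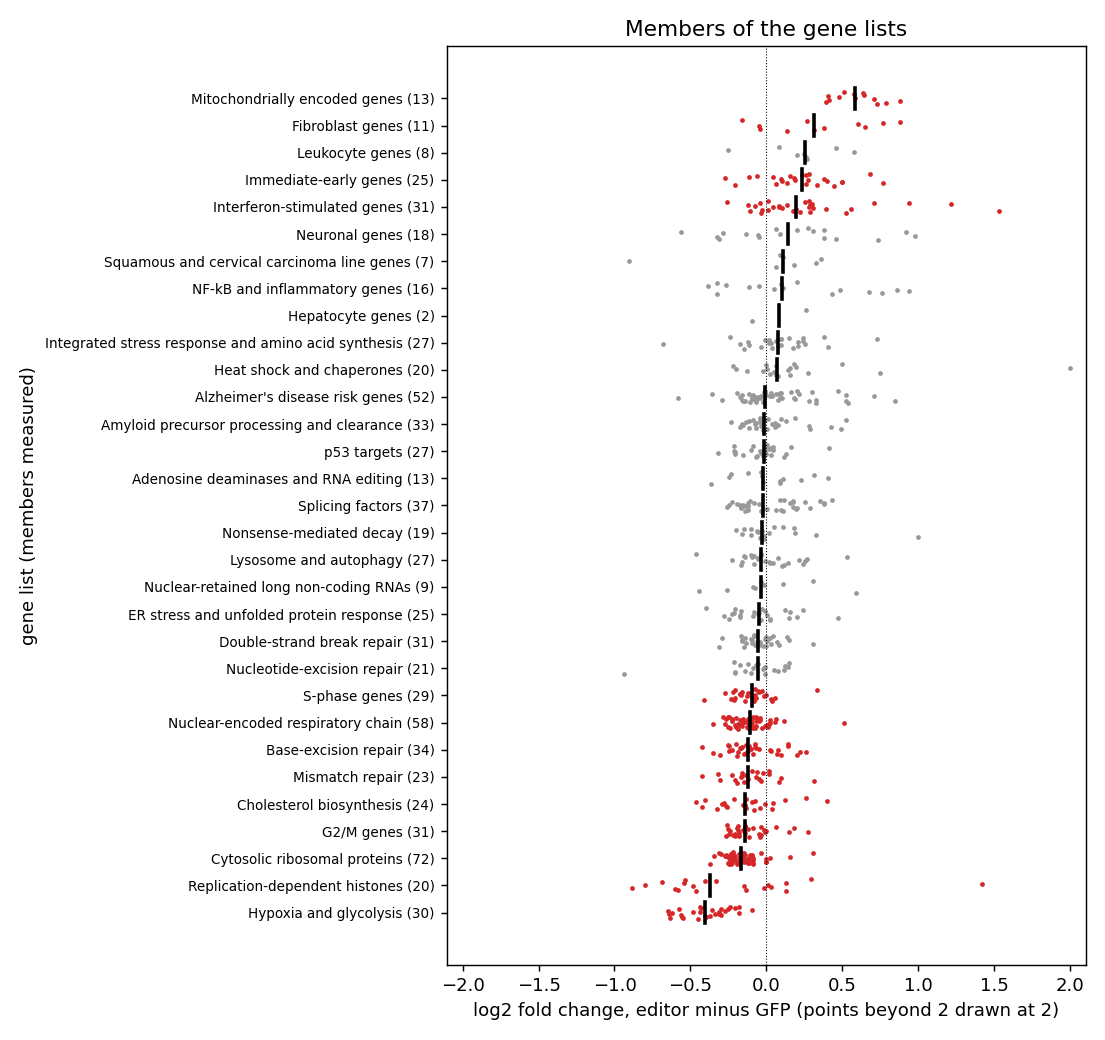
Log2 fold change, editor minus GFP (horizontal axis), of each measured member of the 31 gene lists, with a bar at the median of the list. Red lists passed camera with the preset correlation and grey lists did not. Members of the hypoxia and glycolysis list all lie below 0 and those of the mitochondrially encoded list all above 0.

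Cell cycle lists were lower. S-phase genes (adjusted p = 0.00057), G2/M genes (adjusted p = 0.00318) and replication-dependent histones (adjusted p = 0.00377) passed camera, as did cholesterol biosynthesis genes (adjusted p = 0.00846), and 0 members of any of these passed over all genes or adjusted over the list alone. Only 20 of 45 histone genes were measured, 14 of them below 0. Their member with the smallest p, H2BC9, was higher (log2 fold change 1.42) on 5 to 37 reads per library. Of 29 S-phase genes, 25 were below 0, but the one with the smallest p, UHRF1, was higher (log2 fold change 0.34). With an estimated correlation the adjusted p was 0.173 for S-phase genes and 0.728 for the G2/M, histone and cholesterol lists. For S-phase genes that correlation was -0.014, below the preset 0.01, so members moving together do not explain the loss of that call. The call ended for G2/M genes without editor library 2, editor library 3 or GFP library 3, for cholesterol genes without editor library 2, editor library 3 or GFP library 1, and for histones and respiratory chain genes without GFP library 1. Over the libraries left out, the mean difference ranged from -0.38 to -0.08 for G2/M genes, -0.47 to -0.12 for cholesterol genes, -0.48 to -0.18 for histones and -0.25 to -0.05 for respiratory chain genes, each lowest without editor library 1. In all, 13 of 31 lists passed with the preset correlation, 0 with an estimated one and 4 by fry (hypoxia and glycolysis, mismatch repair, S-phase and fibroblast genes), which asks whether members move in 1 direction on balance.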

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

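All settings but the sum of editor libraries 2 and 3, which was chosen after seeing the data, were set beforehand. HSPA6 kept its direction and its call in all 14 alternative fits (log2 fold change 6.87 to 7.28 over the libraries left out), and APP kept its sign and stayed uncalled in all 14 (-0.277 to -0.0979 over the libraries left out, lowest adjusted p 0.165). The 5 higher and 0 lower genes became 178 and 129 with no low-count filter, 47 and 32 with DESeq2, 3 higher with limma-voom, and 1 higher at an adjusted p of 0.01. At 2-fold the counts were 108 higher and 55 lower with no filter, 22 and 7 with DESeq2, and 3 higher with limma-voom. Leaving out a library gave 1 to 159 higher and 0 to 54 lower, and 1 to 77 higher and 0 to 12 lower at 2-fold. The replicate block left 1 higher call, also at 2-fold. Same-numbered libraries deviated from their group means with r of -0.0485, 0.173 and -0.237, which shows no pairing by number but cannot exclude one. Lists called higher numbered 2 to 5 and lower 6 to 9 over the libraries left out, 0 and 0 with an estimated correlation, and 1 and 3 by fry. The base-excision list, at -0.154 from other genes, was not called with an estimated correlation, nor by fry, which makes no comparison with other genes. It was -0.192 to -0.112 over the libraries left out. The mismatch list was -0.166 with an estimated correlation, where it was not called. Other values changed sign, among them the called immediate-early list (0.132 as reported) and the uncalled inflammatory (0.125) and leukocyte (0.128) lists. The Alzheimer list was 0.00839 with no filter and -0.0385 to 0.013 over the libraries left out. Over the libraries left out, UNG was -0.134 to 0.00133 and PMS2 -0.0281 to 0.174. Over the same fits the immediate-early list was -0.029 to 0.208, integrated stress -0.0588 to 0.0918, decay -0.0993 to 0.0219, non-coding RNA -0.124 to 0.049, squamous -0.0578 to 0.00855, hepatocyte -0.285 to 0.181 and leukocyte -0.126 to 0.184. With the stricter filter the inflammatory list was -0.0444, the integrated stress list 0.0295, the decay list 0.0162 and the squamous list 0.158, which was then called (adjusted p = 0.0461). The integrated stress list was 5.62e-05 with library totals and 0.00193 with DESeq2. With libraries summed, 6 genes were higher, 4 of them shared with the 5, RPL21P120 was not called (adjusted p = 0.0734), nor were the cholesterol and G2/M lists (adjusted p = 0.155 each), and the heat shock list was called (adjusted p = 0.00479). In that fit the decay list was 0.0174, the hepatocyte list -0.0249 and the leukocyte list -0.0926. Causes were not tested. At this depth and spread, simulated log2 changes of 0.5 were recovered in 8% of genes.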

Other observations

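The tests of HSPA7 and of the heat shock list, the counting of editor libraries 2 and 3, the RPL21 level and the RPL21 position were chosen only after the result was seen. Single members of other lists stood apart adjusted over the list alone, and 0 of them over all genes. GADD45B, a stress-inducible gene, stood at 14.8 ± 2.74 against 7.41 ± 1.80 CPM (SD, n = 3 each) in the list of nonsense-mediated decay genes, and DDIT4, an inhibitor of mTORC1 signalling, had a log2 fold change of -0.68 (SE 0.12) in the integrated stress list. GADD45B and DDIT4 passed over all genes with DESeq2 (adjusted p of 0.00235 and 0.00102) and without the low-count filter. Neither list passed camera, with adjusted p of 0.909 and 0.961, and for both the mean, median or test differed in sign. The remaining lists did not pass either, namely NF-kB and inflammatory genes (0.621), ER stress (0.137), adenosine deaminases and RNA editing (0.787), splicing factors (0.745), nuclear-retained long non-coding RNAs (0.815), lysosome and autophagy (0.66), and neuronal (0.294), squamous (0.621), hepatocyte (0.984) and leukocyte genes (0.294). The median and mean also differed in sign for RNA editing, splicing, non-coding RNA and lysosome genes.

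Many protein-coding genes of chromosome 6 between 29 and 33 Mb had nearly no counts. Of 153 such genes, 130 (85.0%) averaged under 10 reads per library, against 27.3% of 19678 elsewhere, and PRPF8, a core splicing factor gene outside that region, had 3 reads or fewer in every library.

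The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 5 genes and the highest other 375, so 2 splits gave as many, and at 2-fold the counts were 5 and 32, again with 2 splits. The split with 375 genes sets editor libraries 2 and 3 and GFP library 1 against the rest, which points to a structure of the samples beyond the groups. For gene lists the real split gave 13 and the highest other 10, and 1 split, the real one, gave as many. The splits that mix the groups gave 2 to 10 lists, so many list calls with the preset correlation also arise without the real grouping.

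HSPA6 and HSPA7 were higher in every editor library. The HSPA7 count was at most 0.0199 of the HSPA6 count, and between 1.44% and 1.99% in the 3 editor libraries, as misplaced HSPA6 reads would give, so the HSPA7 call may add nothing to that of HSPA6. A large even rise of the heat shock list is argued against by its median log2 fold change of 0.0644 without HSPA6. Of the 19 genes left, 15 were above 0, DNAJB1 and HSPH1 among them, so a small general rise stays open. A rise of only some members stays open too. In the whole list, HSPA6 included, 4 genes were higher and 0 lower at an unadjusted edgeR p under 0.05. The GFP control carries neither the editor nor the guides, so editor protein, guides, plasmid load and transfection stress stay open and were not tested.

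The hypoxia and glycolysis list was lower in each editor library, by -0.42, -0.48 and -0.48 against the GFP mean. Removing smooth trends on GC content, transcript length and level kept 74.7% of the difference, which argues against those trends as the whole cause. The other lists, those of DNA repair included, were not checked for such trends. The closeness of editor libraries 2 and 3 does not account for the size of the difference, since editor library 1 alone kept 91.9%, though that is 1 library. Summing the pair kept 98.9%, but with values this alike it could hardly change the mean. The list was still called by camera with the pair summed. A difference in density, oxygen or harvest between dishes could lower these genes, and 0 labels cross the groups, so it cannot be told apart from an effect of the editor.

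A hypothesis for the RPL21 pseudogenes was that deaminated RPL21 RNA is aligned to them. More RPL21 reads are argued against, since RPL21 had a log2 fold change of -0.17 (-0.26 to -0.09 over the libraries left out). Counted from the 5′ end of the RPL21 transcript, RPL21P29 and RPL21P120 share A587G, at a TA step, and no RPL21 pseudogene without it exceeded a log2 fold change of 0.95. The position was taken from these 2, the highest, and only they carry it, so that gap is no test. The same 2 also share T765C, which adenine deamination of that strand would not give, so the position cannot be told apart from other shared differences. They share A376G too, not at a TA step, which 9 pseudogenes carry with log2 fold changes down to -0.14. A general form of the idea, with its prediction written before the result, failed. The filters on pseudogenes, with at least 2 per parent, were not part of that prediction. Across 264 pseudogenes of 78 parents other than RPL21, the log2 fold change moved by -0.13 per A-to-G difference at a TA step. The idea needs a rise (permutation p = 0.0401, two-sided). A fall is given neither by the idea nor by its absence. The treatment of reads with several matches is also unknown, so the failed prediction does not exclude the idea. The fit on 20 RPL21 pseudogenes alone gave 0.47 (permutation p = 0.459) and decides nothing.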
